A study of Rattus norvegicus with 18 samples.

How the data were processed

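RNA was measured in the hearts of 18 male Wistar rats, an outbred laboratory strain, in 3 groups of 6 animals. One group received saline, another doxorubicin with saline (called DOX+saline here), and the other doxorubicin with AICAR (called DOX+AICAR). Per the labels, tissue RNA was purified with a column kit for fibrous tissue, and polyadenylated RNA was made into strand-specific libraries that were read from both ends. Per the submitters' processing notes, reads were converted with bcl2fastq 2.17.1.14, aligned with HISAT2 to the rat genome build Rnor_6.0, and counted per gene with featureCounts from Subread 1.5.0. The HISAT2 version, the annotation release and the strand setting of the counting are not given in the sources used here. Whether reads from overlapping genes and from near-identical gene copies were kept apart cannot be seen from these values.

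The deposited table holds TPM values (transcripts per 1000000, a read count divided by gene length and scaled to a fixed total per library). The authors' TPM values sum to 1000000 in each of the 18 libraries. The table has 32545 rat Ensembl gene identifiers, of which 6667 were at 0 in every library. No column of the table lay outside these samples. Because the total is fixed, a rise of some genes lowers the share of all others, and a fold change is a change of share.

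The table does not pair its identifiers with gene names. The reference gene table used here (assembly GRCr8, 47357 genes) matched 0 of the 32545 identifiers. Before the data were examined, 26 pathway lists and 20 cell type marker lists had been fixed by gene symbol, together with a rule naming 8 genes per direction that required a symbol. With 0 identifiers matched, 0 lists were tested, and shares of mitochondrially encoded and haemoglobin genes were not analysed here. In place of the naming rule, 1 identifier per direction is given for each of the comparisons DOX+saline with saline and DOX+AICAR with DOX+saline. It is the one with the largest fold change among genes past the threshold with a mean of at least 5 TPM in 1 of the 2 groups compared. That number was set after it was seen that the identifiers carry no names. No function is attached to any of them.

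Depth was recovered from the TPM values. The ratio of a gene's values in 2 libraries, divided by the ratio of the libraries' scale factors, is a ratio of whole numbers when whole reads were counted. All 25878 genes with a value above 0 were solved to whole reads within 0.001 reads. Genes seen in few libraries are solved almost whatever the factors, so the informative ones are the 20828 genes above 0 in at least 6 libraries, all solved. With wrong scale factors, a search limited to small read numbers solved 0% of 500 such genes. The 2016 genes seen in 1 library were set to 1 read there. Gene lengths recovered from the same steps were whole within 0.05 bp for 100% of 15617 genes checked, with a median of 2289 bp. On simulated reads of 13743 genes over all 18 libraries, 91.0% of genes came back exactly, as did 99.97% of the 7935 genes present in at least 6 libraries. Recovery was therefore less exact for genes in fewer libraries, which can affect the counts of genes detected at equal depth. Libraries held 20.57 to 31.32 M recovered reads (M, 1000000) assigned to genes. For the number of genes detected, reads were thinned at random to 20.57 M in each library, averaged over 20 draws. These counts carry counting error, and the reads have no molecular identifiers.

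Tests fitted the unit. The design fixed before the data were examined named limma on log2(TPM + 1) for a table of normalized values, and this was used. Genes with at least 1 TPM in at least 6 of the 18 libraries were kept (14732 genes). A linear model with a mean per group and a mean-variance trend was fitted to all 18 libraries at once, so that the 3 comparisons share 1 estimate of each gene's spread. This takes the spread as equal in the 3 groups, while saline libraries were more alike than those of the other groups. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all genes kept, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The test was checked on simulated data for DOX+saline against saline (14070 genes). It called 44% of 50 genes changed 1.5-fold and 100% of 50 genes at each of 2, 4 and 8-fold, with 18 calls among unchanged genes. The simulated genes varied independently, with a variance parameter set at 0.03 in every group. These rates need not hold for the real libraries, whose spread differs between groups.

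Values per library were compared with two-sided exact permutation tests over all 924 assignments of the 12 libraries compared, with Benjamini-Hochberg adjustment over the comparisons of a family. The smallest p such a test can give is 0.00216. Each library was also placed on a doxorubicin axis, the direction in gene space from the saline mean (position 0) to the mean of the 12 doxorubicin libraries (position 1). The 2 comparisons that share the DOX+saline libraries carry those libraries' chance values with opposite signs. Their relation is therefore given beside 100 simulated unchanged sets of groups and beside 20 splits of the 6 DOX+saline libraries into sets of 3, where no library served both comparisons.

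Replicates were compared by a chi-square per gene on recovered reads. It ranged from 9.81 to 19.4 within saline, from 5.05 to 69.0 within DOX+saline and from 16.6 to 33.2 within DOX+AICAR, so no pair agreed within sampling noise. The pair at 5.05 was DOX+saline animals 1 and 6, below every other pair, and the next pair of that group gave 24.05. Whether these libraries are independent was not tested. Each animal was taken as 1 independent library. The groups share no animal numbers, and no samples were paired. The labels give no sequencing batch or date. Saline animals are numbered 51 to 56 and doxorubicin animals 1 to 12, in different number series, so any difference of housing or handling that follows the series cannot be told apart from doxorubicin.

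Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 TPM, median-of-ratios factors, quantile normalization, only the 12 libraries compared, array weights, the library number as a covariate, each animal left out in turn, and the 10 in place of the 50 highest genes. The counts of genes detected, at equal depth as well as without thinning, were not among the planned results and were chosen after seeing the data. Alternatives chosen after seeing the data were voom on the recovered reads with at least 10 reads in at least 6 libraries, counts of genes detected without thinning, the axis position under the same alternatives, and all counts without DOX+saline animals 1 and 6. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.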

Results

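The series asked how AICAR acts in rats whose hearts were damaged by doxorubicin. Doxorubicin is an anthracycline used against cancer that binds DNA, poisons topoisomerase II and injures heart muscle. AICAR is a nucleoside that cells phosphorylate to an AMP mimic, which activates the energy-sensing kinase AMPK. Rats of about 250 g received 5 weekly intravenous injections of saline or of doxorubicin at 3 mg/kg per week. The rats given doxorubicin also received subcutaneous saline or AICAR at 0.5 g/kg. Heart RNA of 6 saline, 6 DOX+saline and 6 DOX+AICAR animals was sequenced, each animal as 1 library. Recovered reads, in units of 1000000 (M), averaged 26.2 ± 4.07 M in saline, 27.4 ± 1.85 M in DOX+saline and 27.4 ± 2.11 M in DOX+AICAR (SD, n = 6 each). The groups' depths did not differ past the threshold (exact permutation p = 0.539, 0.996 and 0.563 for the 3 comparisons). The deposited values are TPM, and genes appear under Ensembl identifiers that the table does not pair with names.

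What doxorubicin did to heart RNA was addressed by DOX+saline against saline. Of 14732 genes tested, 8538 (58.0%) changed at adjusted p below 0.05 (limma), 5595 of them higher and 2943 lower. Large changes were mostly increases: 984 genes were at least 2-fold higher and 107 at least 2-fold lower, and at 4-fold the counts were 207 and 6. In 4751 genes the 6 DOX+saline libraries and the 6 saline libraries did not overlap, where chance gives 0.216% of genes, or 31.9, on average. The balance of directions depended on the scaling. With median-of-ratios factors 51.3% of 8413 called genes were higher, and with quantile normalization 41.0% of 8343, against 65.5% on the values as deposited. Quantile normalization moved the median log2 change of all genes by -0.16. Under all 3 scalings 3153 genes were called higher and 2924 lower, and 2-fold increases outnumbered 2-fold decreases in each (870 against 159 with median-of-ratios factors, 620 against 258 with quantile normalization).

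Most of the 50 most abundant transcripts of the saline heart fell. Of the 50 genes with the highest mean TPM in saline, 42 were lower in DOX+saline, 2 were higher and 6 did not pass the test, with a median log2 change of -0.31. With median-of-ratios factors 42 of them were lower, and with quantile normalization 30. These 50 genes held 21.4% of the TPM total in saline, 17.6% in DOX+saline and 17.7% in DOX+AICAR. They were chosen on the same saline libraries that they are compared with, which by itself can favour falls. Among genes of 500 TPM or more by the mean of all 18 libraries, 154 were lower and 105 higher. Each library's own 50 highest genes held 21.4 ± 1.139% in saline and 19.3 ± 0.762% in DOX+saline (SD, n = 6, exact permutation p = 0.00433, adjusted p = 0.013).

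Scarce transcripts were more often higher than lower, on the values as deposited and with median-of-ratios factors but not with quantile normalization. Among genes with a mean under 5 TPM over the 18 libraries, 1454 were higher and 295 lower in DOX+saline. Among genes of 500 TPM or more, 105 were higher and 154 lower, and 83.5% of them changed. This gradient was also present with median-of-ratios factors (77.1% of calls higher under 5 TPM, 31.9% at 500 TPM or more). Quantile normalization, which gives every library the same distribution, left 38.0% and 43.8%. A set of 178 genes lay below 1 TPM in all 6 saline libraries and at 1 TPM or more in all 6 DOX+saline libraries, and 125 of these met that level in all 12 doxorubicin libraries. The converse held for 8 genes. At an equal depth of 20.57 M reads, 18132 ± 138.5 genes were detected in saline and 19988.5 ± 248.6 in DOX+saline (SD, n = 6), a difference of 1856.5 genes (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00278). On the values as deposited, higher calls outnumbered lower calls in each of 5 bins of gene length, with 61.8% to 68.0% of calls higher.

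**Figure D1:**
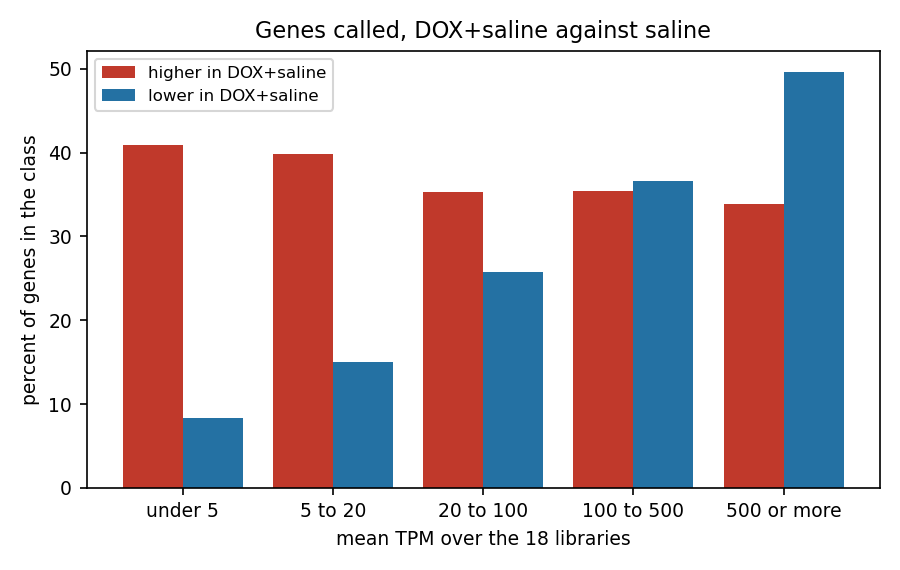
Percent of the genes in each class of mean TPM over the 18 libraries that were called higher (red) or lower (blue) in DOX+saline than in saline, on the values as deposited. Higher calls exceed lower calls under 100 TPM as deposited, which quantile normalization turned in all 3 of these classes and median-of-ratios factors turned between 20 and 100 TPM (1232 higher, 1874 lower), and at 500 TPM or more 105 genes were higher and 154 lower.

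Among genes with at least 5 TPM in 1 of the groups, the largest increase after doxorubicin was that of ENSRNOG00000012404. It averaged 0.138 ± 0.142 TPM in saline and 234 ± 148 TPM in DOX+saline (SD, n = 6), a log2 change of 7.25 (SE 0.57, limma adjusted p = 2.12e-08). The size depended on the scale, at 9.69 with a pseudocount of 0.1 and 10.3 with voom on the recovered reads. The lowest DOX+saline animal reached 24.3 TPM and the highest saline animal 0.361 TPM. In DOX+AICAR it averaged 114 ± 84.5 TPM, which did not differ past the threshold from DOX+saline (log2 change -0.90, SE 0.57, limma adjusted p = 0.424). The largest decrease was that of ENSRNOG00000009227, from 55.6 ± 5.83 TPM in saline to 9.04 ± 1.5 TPM in DOX+saline (log2 change -2.50, SE 0.16, limma adjusted p = 3.28e-09). In DOX+AICAR this gene averaged 16.03 ± 4.93 TPM, higher than in DOX+saline (log2 change 0.72, SE 0.16, limma adjusted p = 0.0412) and lower than in saline (log2 change -1.78, SE 0.16, limma adjusted p = 1.51e-07).

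What AICAR added in rats given doxorubicin was addressed by DOX+AICAR against DOX+saline. Few genes were called between these groups: 196 of 14732 genes (1.33%) changed (limma), 85 higher and 111 lower. Of these, 2 were at least 2-fold higher and 12 at least 2-fold lower. At an unadjusted p below 0.05 there were 2590 genes. The libraries of both groups did not overlap in 222 genes, where chance gives 31.9 on average. Genes vary together, so this count can vary widely by chance, and its spread over other splits was not measured. The fit takes the spread as equal in the 3 groups, but the median chi-square per gene between libraries was 13.5 in saline, 37.4 in DOX+saline and 25.5 in DOX+AICAR. The saline libraries can therefore make the estimate of spread too small for this comparison. The number of called genes was not stable: with only the 12 libraries compared it was 16, with array weights 1058 and with quantile normalization 321. Leaving out 1 animal moved it by more than 1.5 times in 14 of 18 fits, from 36 without DOX+AICAR animal 10 to 461 without DOX+saline animal 2. Higher calls outnumbered lower ones with quantile normalization (165 and 156), with only the 12 libraries compared (9 and 7), without DOX+saline animal 5 (146 and 118), without DOX+AICAR animal 7 (90 and 76) or 12 (45 and 44) and without DOX+saline animals 1 and 6 (154 and 118).

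The gene with the largest increase after AICAR was ENSRNOG00000005247, at 2.13 ± 0.622 TPM in DOX+saline and 49.3 ± 9.41 TPM in DOX+AICAR (SD, n = 6, log2 change 4.01, SE 0.64, limma adjusted p = 0.0107). The groups did not overlap, with 3.31 TPM the highest in DOX+saline and 39.2 TPM the lowest in DOX+AICAR. Saline animals fell on both sides, since animals 52 and 54 had 35.4 and 57.5 TPM and the other saline animals 1.56 to 3.48 TPM. This split among saline animals enters the shared estimate of spread and widens it for this gene. With only the 12 libraries compared, its log2 change was again 4.01 and its limma adjusted p was 1.37e-08. The largest decrease was that of ENSRNOG00000011705, from 6.10 ± 3.92 TPM in DOX+saline to 0.486 ± 0.380 TPM in DOX+AICAR (log2 change -1.97, SE 0.39, limma adjusted p = 0.0272). It had risen after doxorubicin from 0.0684 ± 0.0279 TPM in saline (log2 change 2.41, SE 0.39, limma adjusted p = 5.44e-05), and DOX+saline animal 2 stood at 0.246 TPM. The AICAR call on this gene was lost without DOX+AICAR animal 9 (limma adjusted p = 0.0564) or 10 (0.0689), with only the 12 libraries compared (0.099) and with voom on the recovered reads (0.119). Its log2 change was -1.99, -1.93 and -1.97 in the limma fits on TPM among these, close to the main -1.97, while the adjusted p rose. With voom it was -3.19. The size depended on the scale, at -2.99 with a pseudocount of 0.1 and -2.39 with 0.5. It did not pass the filter on low values in 8 of 29 alternatives, among them those without DOX+saline animal 1, 3, 4, 5 or 6 and without DOX+AICAR animal 11. Its adjusted p ranged from 0.000141 to 0.119 over the alternatives.

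**Figure D2:**
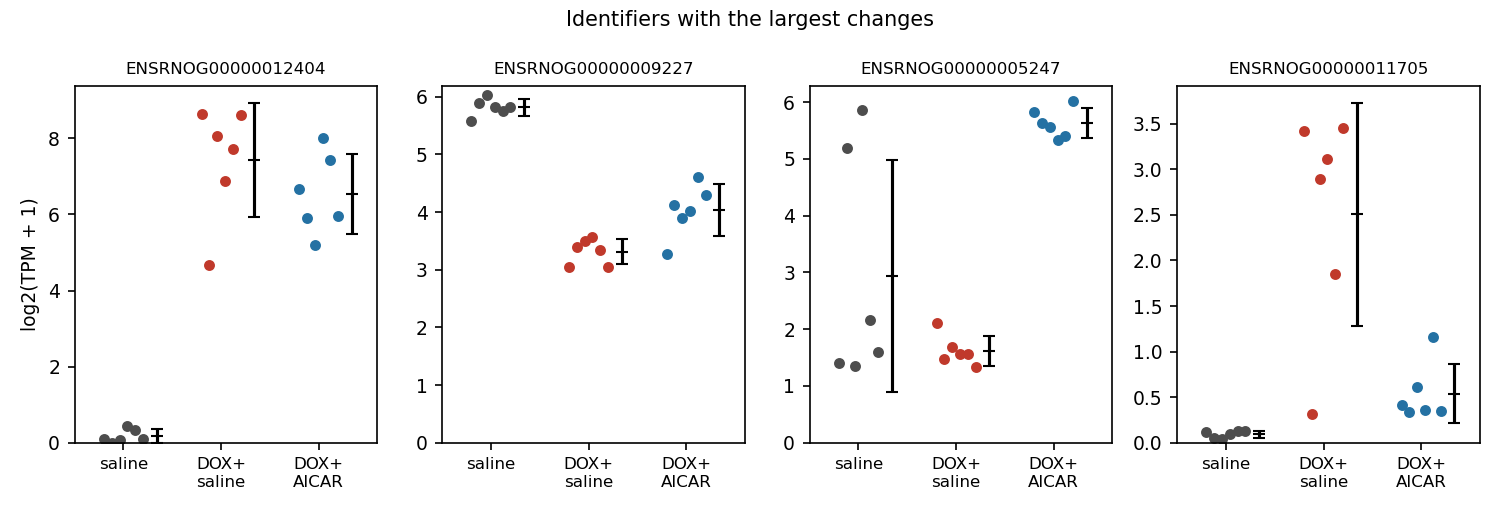
Each point is 1 animal's log2(TPM + 1) for the 4 identifiers named in the text, by group, with the mean and SD of the 6 animals as a bar beside them. ENSRNOG00000012404 is near 0 in all saline animals, and ENSRNOG00000005247 is high in all 6 DOX+AICAR animals and in saline animals 52 and 54.

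Fewer genes had at least 1 read after AICAR at equal depth, a measure chosen after seeing the data. DOX+AICAR libraries had 19683.5 ± 120.7 genes, between 19499 and 19825, and DOX+saline libraries between 19855 and 20491 (SD, n = 6, difference -305 genes, exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00278). Without thinning the difference was -309.8 genes (exact permutation p = 0.0758), and at 1 TPM or more it was -258.5 genes (exact permutation p = 0.0519, adjusted p = 0.0584). With at least 10 reads at equal depth the groups overlapped, at 14660 to 14928 genes in DOX+AICAR and 14726 to 15410 in DOX+saline. The share of the 50 highest genes was 19.4 ± 0.820% in DOX+AICAR and differed from DOX+saline by 0.0594 percentage points (exact permutation p = 0.892).

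**Figure D3:**
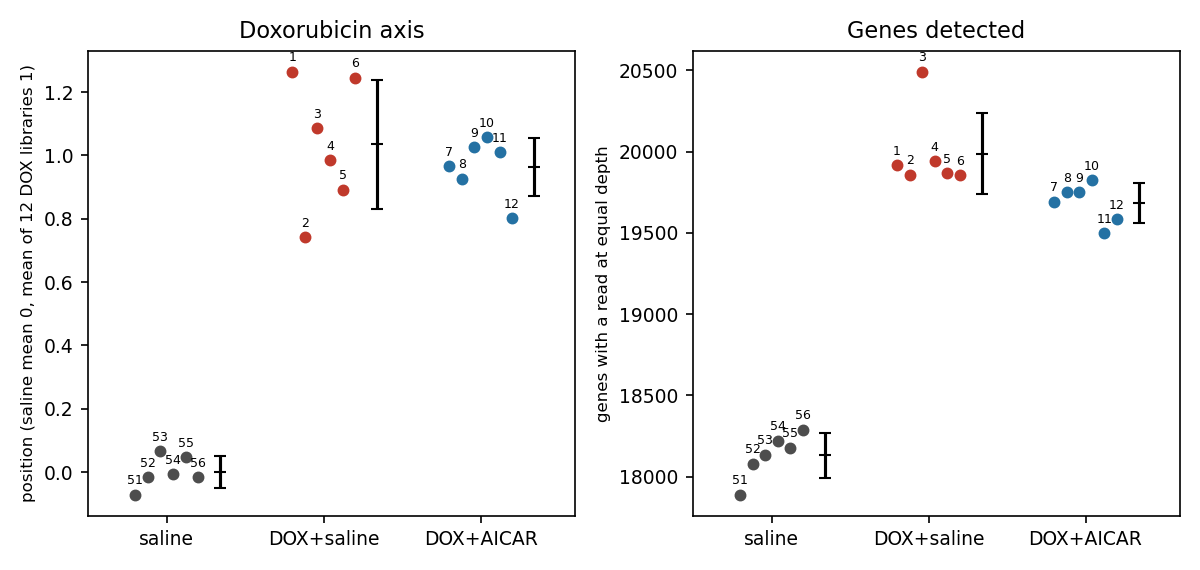
Left, position of each animal's library on the doxorubicin axis (saline mean 0, mean of the 12 doxorubicin libraries 1, no unit). Right, genes with at least 1 read at an equal depth of 20.57 M reads. Points are animals with their numbers, and bars are the mean and SD of 6 animals. All doxorubicin animals lie above all saline animals in both panels. The axis was built from these same libraries, so the separation on the left is largely built in. DOX+saline animals spread from 0.742 to 1.264 on the axis.

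Whether AICAR moved the genes changed by doxorubicin back was asked gene by gene. Of the 8538 genes changed by doxorubicin, 161 (1.89%) were called in the opposite direction after AICAR and 17 in the same direction. The 161 were 82.1% of the AICAR calls, and they rest on the same shared estimate of spread. This set was not stable: leaving out 1 animal moved its size by more than 1.5 times in 14 of 18 fits, from 27 without DOX+AICAR animal 10 to 420 without DOX+saline animal 2, and array weights gave 943. On all 18 libraries they comprised 100 genes that rose after doxorubicin and were lower with AICAR, and 61 genes that fell and were higher with AICAR. Independent lists of these sizes give 42.2 and 16.98 genes. Of them, 97 were still called against saline on the doxorubicin side, 63 were not called and 1 was called on the other side.

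The comparisons share the DOX+saline libraries, which pushes their fold changes apart without any effect. Across genes, which are not independent replicates, the correlation of the fold changes was -0.355, against a mean of -0.564 in simulated unchanged groups. The central interval of the 100 draws, without the extremes, was -0.855 to -0.233. The covariance was -0.0491 against a simulated -0.0176 (central interval -0.0507 to -0.0041), a difference of -0.0314. Both observed values lay inside these intervals. With the DOX+saline libraries split so that none served both comparisons, the mean covariance was -0.0315 over 20 splits, from -0.0678 to 0.0270, and it was below 0 in 17. Over these splits 1948 calls were opposite and 583 in the same direction, with medians of 25.5 and 4 per split. The splits reuse the same 6 libraries, so they are not independent and a gene can be counted in several. In those splits the slope across genes of the AICAR change on the doxorubicin change averaged -9.75%, from -23.6% to 5.57%. A slope is set mostly by genes with large doxorubicin changes, and 57.4% of genes had opposite signs. Without DOX+saline animals 1 and 6, the most alike pair of libraries, 113 genes were called opposite and 80 the same way, and 63 of the 161 genes were among the 113. These animals also had the highest positions of their group on the doxorubicin axis, so leaving them out brings the DOX+saline mean nearer to saline.

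**Figure D4:**
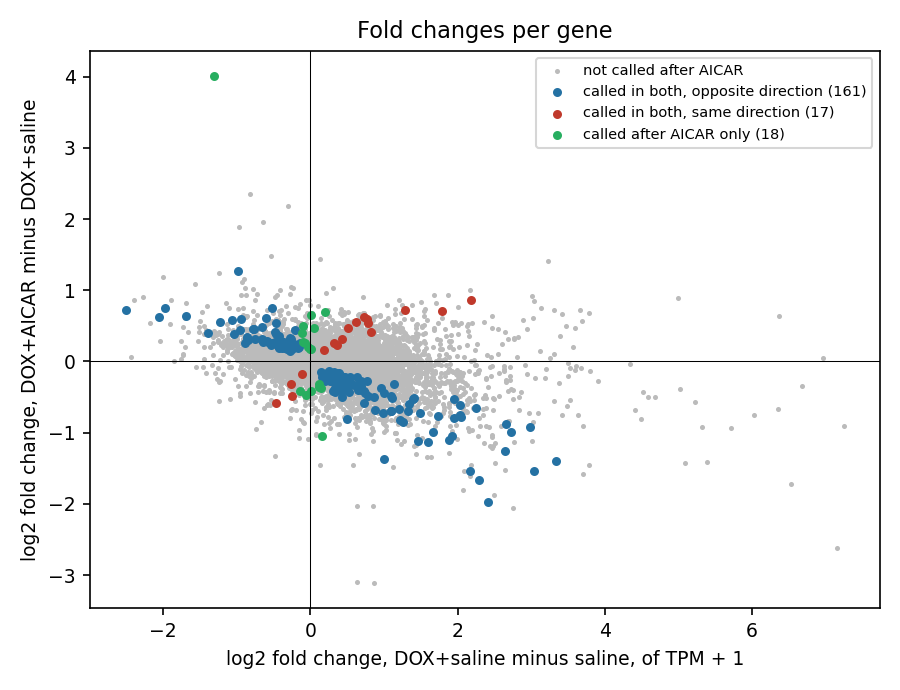
Each point is 1 of 14732 genes, with its log2 fold change of TPM + 1 after doxorubicin (x axis) and after adding AICAR (y axis). Blue marks the 161 genes called in both comparisons in opposite directions, red the 17 called in the same direction and green the 18 called only after AICAR. The shared DOX+saline libraries tilt this cloud downward with no effect of AICAR.

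On the doxorubicin axis, DOX+saline libraries averaged 1.04 ± 0.204 and DOX+AICAR libraries 0.964 ± 0.0918, while saline libraries lay between -0.0711 and 0.0657 (SD, n = 6). The AICAR group differed by -0.0711, which did not pass the threshold (exact permutation p = 0.455). The sign turned without DOX+saline animals 1 and 6 (0.0446, exact permutation p = 0.567), which lay highest in their group, so that leaving them out lowers its mean. It also turned without animals 1 and 3 (0.0093) and without 3 and 6 (0.0054), of 15 pairs left out. The axis shows only differences along the doxorubicin direction. On the second principal component, a direction of spread among all 18 libraries found without the group labels, the 2 doxorubicin groups did not overlap. It held 6.5% of the variance. DOX+saline libraries lay from -31.58 (animal 3) to -1.48 on it, and DOX+AICAR libraries from 3.86 to 23.55. This separation was not tested.

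DOX+AICAR against saline showed what separated rats given both drugs from rats given saline. Here 7850 of 14732 genes (53.3%) changed (limma), 5133 higher and 2717 lower, with 911 at least 2-fold higher and 72 at least 2-fold lower (788 and 109 with median-of-ratios factors, 583 and 162 with quantile normalization). With median-of-ratios factors 49.96% of 7872 calls were higher, and with quantile normalization 40.5% of 7910, against 65.4% as deposited. Under all 3 scalings 3001 genes were higher and 2693 lower. Of the 50 highest genes in saline, 41 were lower and 4 higher, and with quantile normalization 32 were lower. DOX+AICAR libraries detected 1551.5 more genes than saline at equal depth (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00278).

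The genes changed by doxorubicin with and without AICAR overlapped. In both comparisons with saline 4471 genes were higher and 2367 lower, where independent lists give 1949 and 543, and 1 gene was called in opposite directions. These comparisons share the saline libraries. The correlation of their fold changes across genes was 0.918 against 0.385 in simulated unchanged groups, and the covariance 0.300 against 0.00966. Simulated unchanged groups shared 0 calls. With the saline libraries split so that none served both comparisons, the mean correlation was 0.854 and the mean covariance 0.288 over 20 splits. All saline rats carry another number series than the doxorubicin rats. A difference between cohorts would therefore remain in both comparisons, and these splits cannot tell it from doxorubicin.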

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

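The values here were picked by a fixed rule on the gap between an extreme animal and its group. Of 24 groups of 6 values tested, 2 were picked, and chance picks about 1 in 20 groups, or 1.2 here.

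DOX+saline animal 3 stood apart in the number of genes detected at equal depth, at 20491 genes, where the other 5 animals of its group had 19855 to 19941. Without this animal the DOX+saline libraries still lay above the highest DOX+AICAR library, at 19825 genes.

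DOX+AICAR animal 11 had 1.23 TPM of ENSRNOG00000011705, where the other 5 animals of its group had 0.268 to 0.534 TPM. DOX+saline animals ranged from 0.246 to 9.95 TPM, and animal 2, the lowest of them, lay below all 6 DOX+AICAR animals.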

How the results depend on the processing

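Voom on recovered reads, all counts of genes detected (at equal depth and without thinning), the axis position under alternatives and all values without DOX+saline animals 1 and 6 or another pair were chosen after seeing the data. Counts of changed genes stayed within 1.5 times in all 29 alternatives for DOX+saline against saline (7000 to 10014) and for DOX+AICAR against saline (6541 to 8722). Leaving out each animal gave 7902 to 8710 and 7275 to 7981. ENSRNOG00000012404, ENSRNOG00000009227 and ENSRNOG00000005247 kept their calls in all 29 alternatives, and ENSRNOG00000011705 in 17 of the 21 in which it passed the filter.

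For DOX+AICAR against DOX+saline, 196 calls became 16 with only the 12 libraries compared, a fit that leaves out the saline libraries' share of the spread estimate, 321 with quantile normalization and 1058 with array weights. The 161 genes moved back became 246 with quantile normalization and 943 with array weights. The array weights of DOX+saline animals 1 and 6 were 1.84 and 1.76, and those of the other DOX+saline animals 0.314 to 0.538. Leaving out each animal gave 36 to 461 calls and 27 to 420 genes moved back. Moves beyond 1.5 times came without saline animals 52 to 56 (130, 105, 106, 108 and 126 calls, of which 106, 85, 84, 88 and 103 moved back), without DOX+saline animals 1, 2, 3, 4 and 6 (49, 461, 43, 121 and 48 calls, of which 35, 420, 36, 104 and 35 moved back) and without DOX+AICAR animals 9 to 12 (39, 36, 60 and 89 calls, of which 32, 27, 52 and 66 moved back). The cause was not tested.

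The axis position of DOX+AICAR relative to DOX+saline ranged from -0.125 without DOX+saline animal 2 to -0.0212 without DOX+saline animal 1, with p from 0.149 to 0.816 by exact permutation, and turned to 0.0446 without DOX+saline animals 1 and 6, the highest of their group on this axis. Of all 15 pairs of DOX+saline animals left out, 3 turned the sign (0.0093 without 1 and 3, 0.0054 without 3 and 6), with a range of -0.168 to 0.0446. The AICAR difference in the share of the highest genes, 0.0594 points for 50 genes, was -0.104 points for 10 (exact permutation p = 0.708). The AICAR difference in genes detected lost its call without thinning (-309.8, exact permutation p = 0.0758), where depth differs between libraries. Not run were the alternatives that need a table of counts, and those that need gene symbols, which are the one leaving out mitochondrially encoded genes and the gene list tests. Changes of 1.5-fold were called in 44% of simulated genes, whose variance parameter was set at 0.03 and not taken from these data. That share need not be the sensitivity of the real fit. There, genes called after doxorubicin had a median log2 change of 0.456 (higher) and -0.3505 (lower). Small changes can still go uncalled.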

Other observations

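The tests of genes detected, of the 2-fold changes, of the share of opposite calls over other splits, of DOX+saline animals 1 and 6 and the other pairs, of the spread among the DOX+saline animals and of library-specific genes were chosen after the results were seen.

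Some genes were high in 1 animal alone. In DOX+saline animal 3, 84 genes had at least 5 TPM and at least 4 times the value of every other library, and together they made up 2832 TPM. In each of the other 17 libraries 0 to 7 genes met this. The AICAR calls were split unevenly by gene length, without a test: in the shortest of 5 length bins, 1104 bp or less, 7 genes were higher and 24 lower with AICAR, and in the longest bin 21 were higher and 20 lower.

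Genes changed by doxorubicin were mostly higher, 5595 against 2943. A fixed total, in which all other genes gain share when the most abundant lose it, shifts all genes alike and does not account for the 2-fold changes, of which 84.5% were still higher after median-of-ratios scaling (870 against 159). For the smaller changes it stays open, since that scaling centres the changes and so sets the 51.3% of all calls that were higher. A smaller share of the cells that make the most abundant RNAs stays open: 84% of the 50 genes highest in saline fell and 4% rose, and marker genes were not tested by name. Those 50 genes were picked on the saline libraries, which can favour falls. A separate cohort of saline rats stays open too, since 0 saline rats carry a number in the series of the doxorubicin rats.

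Genes changed by AICAR mostly went against doxorubicin, 161 against 17, or 90.4% opposite. How much of this comes from the shared DOX+saline libraries stays open. With no library shared, 1948 calls were opposite and 583 the same (77.0% opposite), summed over overlapping splits that can count a gene more than once. Single splits gave up to 725 of the former and up to 274 of the latter. The covariance was below 0 in 17 of 20 splits, where 18 had been set as the bound. Other splits of the 12 doxorubicin libraries do not settle it, since 83 of 99 gave no call, 7 had 10 or more shared genes, and 1 split gave 924 of the 1187 opposite calls behind a pooled 98.3%. Dependence on 1 animal stays open, since the ratio of opposite to same-direction calls, at least 4.12 without any 1 animal, can be held up by the shared libraries, while the counts fell to 27 against 4 without DOX+AICAR animal 10. Without DOX+saline animals 1 and 6 the ratio was 1.41, against 2.6 to 42.7 for the other pairs of that group with 10 or more shared genes. These animals lie highest on the doxorubicin axis (1.264 and 1.245), so a lower ratio can follow in part from leaving them out, which was not tested.

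DOX+saline animals spread widely on the doxorubicin axis, from 0.742 to 1.264. Unequal depth is argued against, since recovered reads ranged over 5.03 M in DOX+saline and over 10.75 M in saline, whose animals lay close together. One hypothesis is that hearts varied more after doxorubicin alone than with AICAR. The mean absolute deviation was 0.1625 in DOX+saline and 0.0665 in DOX+AICAR (exact permutation p = 0.0758), which leaves it open with 6 animals per group.

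Other splits of the same 12 libraries into 6 and 6 were drawn, 100 per comparison with the real one included. For DOX+saline against saline the real split gave 8538 genes and the highest other 6319, and 1 split of 100 gave as many. For DOX+AICAR against saline the real split gave 7850 and the highest other 4471, and again 1 of 100 gave as many. In both cases that was the real split itself, the smallest share that 100 splits can give. Chance assignment is argued against for both, to the limit of the splits drawn. For DOX+AICAR against DOX+saline 2 of 100 splits gave as many as the real 196, the real split and 1 other. This does not exclude chance, since only 100 splits were drawn and the count of calls was not stable. The highest other split gave 1025, several times the real count, which points to a structure of the samples. That split set DOX+saline animals 1 and 6 with DOX+AICAR animals 8, 9, 10 and 11, at a mean position of 1.09 on the doxorubicin axis, against 0.912 for the other 6 animals.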
